A study of Homo sapiens with 4 samples.

How the data were processed

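RNA from K562 cells was sequenced in 4 libraries, 2 with a scrambled control siRNA and 2 with an siRNA against HMRHL, 36 hours after transfection. Per the submitters' processing notes, the tools were Trim Galore 0.4.4, Bowtie2, TopHat, SAMtools 1.3.1, Cufflinks and Cuffdiff, and the genome builds named were GRCh38 and hg38. Those notes, as used here, hold tool names and versions only, without order, settings or threshold. A single table was analysed, holding a gene symbol and 1 fold change per row, which the authors made from both groups together and deposited under a title that names differentially expressed protein-coding genes. The deposited fold change column carries no unit. These values, made by the authors before they were deposited, were read as log2 because both signs occur, because no value exceeds 6 significant digits (755 of 831 values have exactly 6), which is how Cuffdiff prints its log2 column, and because no rule in the labels gives another scale. A signed linear fold change cannot be excluded, since no value lies between -1.15 and 1.50. The direction was read as knockdown relative to scramble, which the deposited table does not state. If the scale or the direction were read the other way, sizes or signs would change throughout.

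The table lists only selected genes, and the authors' threshold is not given in the sources used here. Counts or expression levels per library, p-values and the tested but unselected genes were not analysed here. For this reason no differential test, replicate error, confidence interval from depth or enrichment test was made. With 2 libraries per group, and no statement that they came from separate cultures, the authors' selection may rest on technical spread.

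Rows were read as deposited and, for all analyses by gene, each symbol was counted once, since repeated rows carried identical values. Symbols were matched to GENCODE release 29 (GRCh38), the build named in the processing notes. Of 742 symbols, 740 matched directly, 1 through an older symbol and 1 (AC097662.2) not at all; 740 were annotated as protein-coding and 1 (FAM182B) as a lincRNA. Coordinates are 1-based and are those of this annotation. Near-identical copies were sought with BLAST 2.17.0 by comparing the longest transcript of each gene with all annotated transcripts of genes that do not overlap its locus, at 95% identity over at least 50% of its length; 20 genes had one. Exons of 277 genes overlap exons of a gene on the opposite strand and those of 43 genes overlap a gene on the same strand.

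Gene lists were made partly from symbol patterns and are not complete families. The tests, the alternatives, 37 gene lists and the rule for naming genes were set before the data were examined, except where stated. Named are PHKB and HMRHL if listed, the 10 most positive and 10 most negative values, and the 4 members of each list with the largest absolute values. Some genes that this rule selects, and 1 of the lists, are not reported here. Further parts of this rule needed expression levels and were not used. The listed genes nearest to PHKB were also set to be named. Repeated symbols, genes with near-identical copies and the families in the closing section were named in addition, after their values were seen. For lists with at least 5 members, the higher and lower counts were compared with those of all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment; chromosomes with at least 5 genes were treated likewise. Differences in gene properties and the directions of neighbouring genes were tested with 100000 permutations of the directions. Intervals of shares are exact binomial 95% intervals across genes, which are not independent replicates. The tests were tried on simulated directions for the 742 genes (p under 0.05, unadjusted). The list test called 200 of 200 lists of 20 genes all set to higher and 7 of 200 unchanged ones. This does not describe its power for shorter lists or toward lower. The neighbour test called 200 of 200 runs in which many pairs were set to share a direction, and 9 of 200 unchanged ones. The property test called 197 of 200 runs in which spans of higher genes were raised by 1 log2 unit, and 44 of 1000 unchanged ones. Both planted effects were larger than the differences observed here, so these counts do not describe power at the observed size. Alternatives were a minimum of 4-fold, each symbol counted once, older symbols translated, and, added later, an equal minimum in both directions, leaving out genes with near-identical copies and leaving out olfactory receptors. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.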

Results

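The study asked how the transcriptome of K562 cells changes when the long non-coding RNA HMRHL is silenced. K562 is an established human cell line from chronic myelogenous leukaemia that carries the BCR-ABL1 fusion. HMRHL is the human counterpart of the mouse RNA mrhl and lies in an intron of PHKB, which encodes the beta subunit of phosphorylase kinase. Cells received a scrambled control siRNA or an siRNA against HMRHL, and total RNA was taken 36 hours after transfection. There were 2 libraries in each of the 2 groups, 4 in all, made with a stranded protocol. The labels do not say whether the 2 libraries of a group came from separate cultures. The values analysed here are 1 fold change per gene from the authors' deposited table of differentially expressed protein-coding genes. They come without an error, a p-value, an expression level or a value per library, so the spread between replicates and the depth behind each value are unknown. Positive values were read as higher in the knockdown and all values as log2, neither of which the table states.

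After the transfection with the HMRHL siRNA, the authors' deposited table listed 227 gene symbols as higher and 515 as lower than in the scramble control. The higher genes were led by POU2F2, a transcription factor of B cells, and LDLRAD4, an inhibitor of TGF-beta signalling, at 5.91 and 5.40 on the log2 scale in the authors' deposited table. The lower genes were led by FRY, a large microtubule-binding protein, at -6.42, and GNA15, a G protein alpha subunit of blood cells, at -5.39 in the authors' deposited table. Read as log2, the outermost values in the authors' deposited table correspond to 60.2-fold for POU2F2 and 85.4-fold for FRY. PHKB, the host gene of HMRHL, was not among the 742 symbols, and HMRHL itself had no entry in this list of protein-coding genes. The knockdown of the target therefore could not be checked from these values.

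Also among the 10 highest values in the authors' deposited table were FAM83F (4.95), FAM84B (4.58), SRPX2 (4.17), OR52A1 (4.10), C1orf167 (3.99), HNF4G (3.98) and AC097662.2 (3.97). SRPX2 is a secreted protein, OR52A1 an olfactory receptor and HNF4G a nuclear receptor. The other 8 with the lowest values in the authors' deposited table were GABBR2 (-5.14), DGKI (-5.02), CYP2F1 (-4.84), PDK2 (-4.83), SPATA6 (-4.77), ENAM (-4.29), ZIC1 (-4.16) and NRIP2 (-4.06). GABBR2 is a subunit of the GABA-B receptor, DGKI a diacylglycerol kinase, CYP2F1 a cytochrome P450, PDK2 a pyruvate dehydrogenase kinase and ZIC1 a developmental zinc finger factor. In GENCODE release 29 on GRCh38, POU2F2 spans chromosome 19 from 42086110 to 42196585 on the minus strand, and FRY spans chromosome 13 from 31846713 to 32299122 on the plus strand. GNA15 spans chromosome 19 from 3136193 to 3163769, and LDLRAD4 spans chromosome 18 from 13217498 to 13652755, both on the plus strand. Of the 20 genes with the outermost values, 13 have exons that overlap exons of a gene on the opposite strand, and 2, among them FRY, overlap a gene on their own strand. Over all 742 symbols these counts were 277 and 43, so opposite-strand overlap was more frequent among the outermost values. This difference was not tested, gene length was not accounted for, and AC097662.2 has no position. Whether the authors' counting used strand is not given in the sources used here, so reads from such overlaps could be shared.

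**Figure D1:**
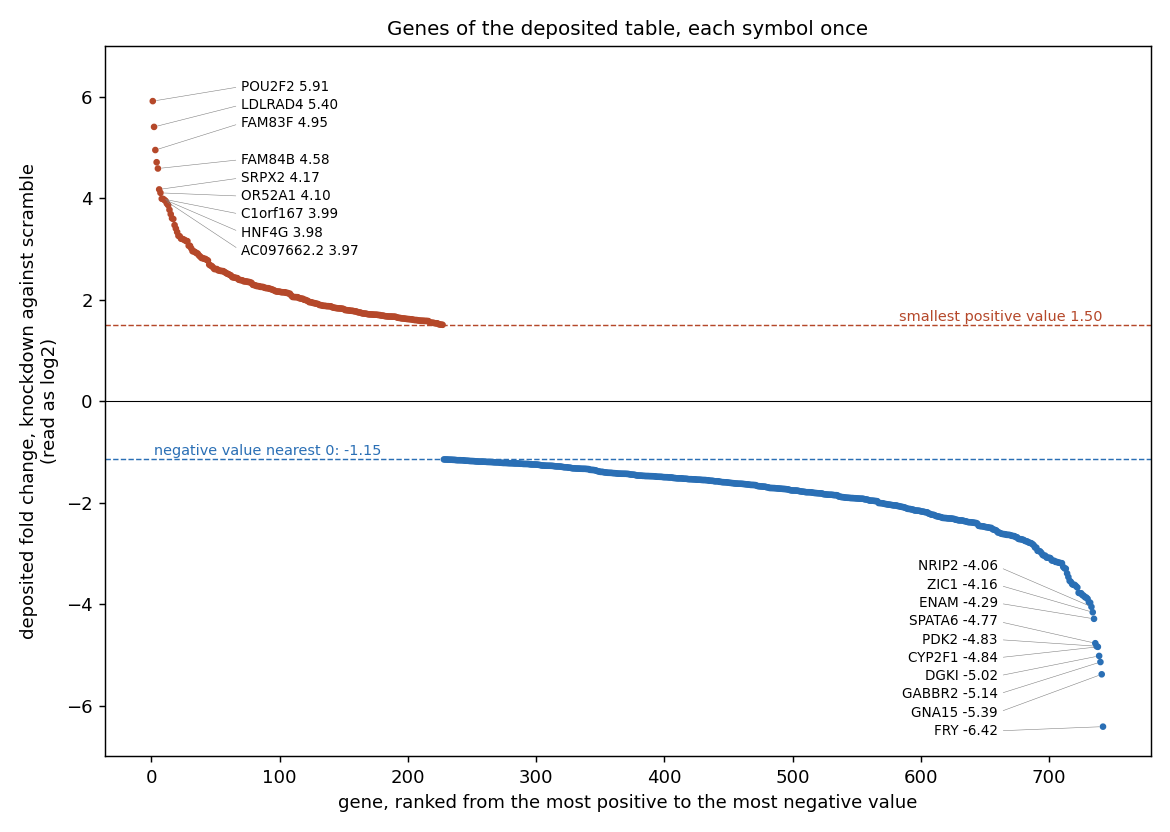
The 742 gene symbols of the authors' deposited table, ranked on the x axis, with their fold change read as log2 on the y axis; red points are higher and blue points lower in the knockdown, and most of the 10 outermost genes on each side are named. Positive values start at 1.50 and negative values at -1.15 (dashed lines), and the range runs from -6.42 for FRY to 5.91 for POU2F2.

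The authors' deposited table had 831 rows, 239 positive and 592 negative, because 37 symbols filled several rows with an identical value. Counted once per symbol, 69.4% of the genes were lower. The entry into the authors' deposited table differed by direction: the smallest positive value was 1.50 (2.84-fold) and the negative value nearest to 0 was -1.15 (2.22-fold). Of the 515 lower symbols, 176 lay nearer to 0 than any higher gene. At an equal minimum of 1.50 in both directions, chosen after seeing the data, 227 higher and 339 lower symbols remained, and the share of lower genes was 59.9%. The median absolute log2 value in the authors' deposited table was 2.05 for higher genes (interquartile range 1.71 to 2.54) and 1.71 for lower genes (1.41 to 2.27). At the equal minimum these medians were 2.05 and 2.03, so the unequal entry minimum accounts for nearly all of this difference. At least 4-fold changes were listed for 118 higher and 176 lower symbols, counted from the authors' deposited table. These are counts of genes that the authors had already selected, and no test for change could be repeated on them.

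Secreted signals and their receptors were listed in both directions. Among cytokines, chemokines and their receptors, 3 members were higher and 6 lower. IL1B, a proinflammatory cytokine, stood at -3.97, CCR4 (a chemokine receptor) at 3.77, CXCL1 at 2.36 and CXCL10 at -2.28 in the authors' deposited table. Among Notch and Hedgehog genes, 3 were higher and 2 lower, with the Notch ligand JAG1 at -3.17, the receptor NOTCH3 at 2.87 and the Hedgehog effector GLI1 at 1.53 in the authors' deposited table. Of the Wnt pathway, 2 members were higher and 4 lower, with the secreted antagonist SFRP5 at -2.19, the R-spondin receptor LGR5 at 1.87, the ligand WNT8B at -1.69 and LGR6 at 1.55 in the authors' deposited table. The list of growth factors and TGF-beta and BMP family genes, which also holds inhibitors of this signalling, had 1 higher and 3 lower members. The authors' deposited table gave the BMP antagonists GREM1 and CHRD at -2.09 and -1.53, and the Nodal inhibitor LEFTY2 at -1.57. The growth factor BDNF was at 1.88 there. Of the receptor tyrosine kinases, PDGFRB was at -3.40 and EPHA5 at 2.36 in the authors' deposited table, and no others of the 53 annotated members appeared. At the share of all annotated protein-coding genes that were listed, 2.0 members would appear. PDGFRB spans chromosome 5 from 150113837 to 150155872. LEFTY2 shares sequence with LEFTY1, so its reads may belong to either gene.

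The gene lists were fixed beforehand, partly by symbol patterns, and are not complete families. Where a second split is given, it is that at the equal minimum of 1.50. This minimum removes only lower genes, and took the share of lower genes among all symbols from 69.4% to 59.9%. Of the solute carriers and ABC transporters, 7 were higher and 22 lower; SLC22A31 was at -3.79, SLC22A11 at -3.17, SLC5A12 at -3.04 and SLC25A2 at -2.84 in the authors' deposited table. Of the ion channels, 7 were higher and 13 lower, and 7 higher and 6 lower at the equal minimum. The calcium channel CACNA1A was at 3.47, the glutamate receptor subunit GRIA4 at 3.15, the potassium channel subunit KCNE4 at -2.66 and KCNT1 at -2.50 in the authors' deposited table. The G protein-coupled receptor list, 10 of whose 19 members are olfactory receptors, had 2 higher and 17 lower, and 2 higher and 6 lower at the equal minimum; OR52A1 was at 4.10, ADGRG3 at -2.39, ADGRG5 at -2.22 and GPR37 at -2.18 in the authors' deposited table. That list misses other receptors of this class in both directions, so its split is not that of the class. Higher ones in the authors' deposited table include CCR4 (3.77), LGR5 (1.87) and LGR6 (1.55). Lower ones there include GABBR2 (-5.14), VIPR1 (-2.62), OPN1SW (-2.19), PTAFR (-2.06) and FPR2 (-1.78). These are examples, and the missed receptors were not counted by direction. The neuronal and synaptic list had 3 higher and 2 lower members, with NRXN3 at -2.09, CNTNAP2 at 1.81, SYN2 at 1.59 and NRXN2 at 1.52 in the authors' deposited table.

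Matrix and adhesion genes appeared in both directions. Of extracellular matrix and matrix enzyme genes, 7 were higher and 8 lower, but 7 and 6 at the equal minimum; the collagen chain COL11A2 was at 3.25, the proteoglycans SPOCK2 and SPOCK1 at -2.39 and -2.35, and the laminin chain LAMA2 at 2.38 in the authors' deposited table. Of cell adhesion molecules, 5 were higher and 5 lower, and 5 and 2 at the equal minimum; the cadherin CDH12 was at -2.79, the integrin ITGA10 at 2.51, PCDH12 at 2.29 and CEACAM18 at 2.23 in the authors' deposited table. The cytoskeleton and motor protein list had 3 higher and 11 lower members, with the unconventional myosin MYO10 at -2.80, TNNC1 at -2.34, MYH11 at -2.30 and MYH3 at 2.23 in the authors' deposited table.

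**Figure D2:**
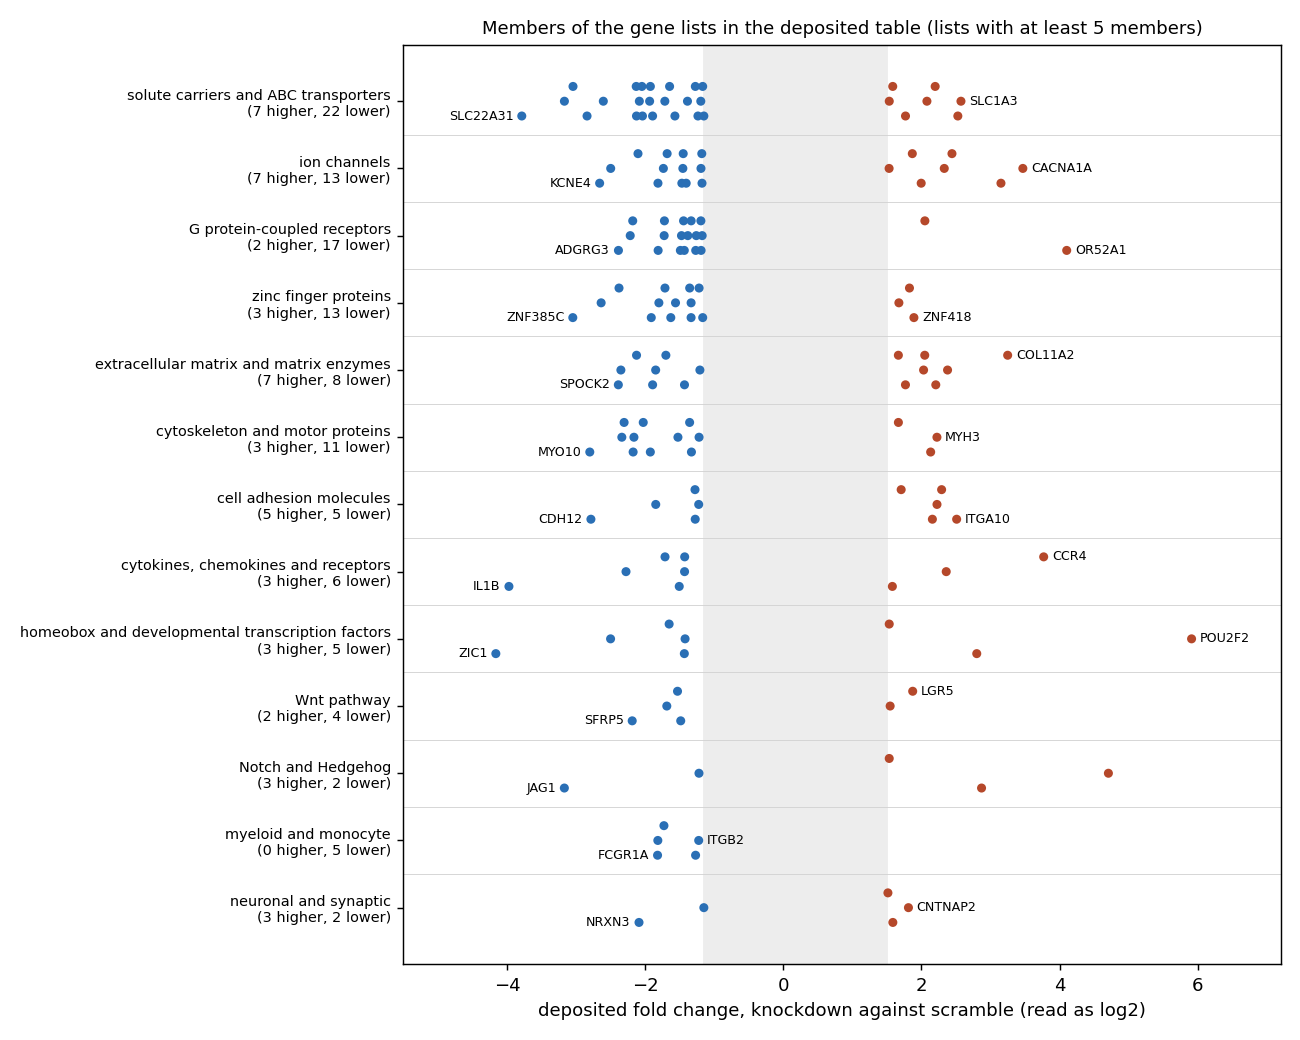
Members of the 13 gene lists with at least 5 genes in the authors' deposited table, one row per list, with the fold change read as log2 on the x axis; red points are higher and blue points lower, the vertical offset within a row only separates points, and the grey band runs from -1.15 to 1.50, where the table holds no value. The lowest and highest member is named in most rows; all 5 members of the myeloid list lie on the lower side, 2 of them nearer to 0 than any higher gene.

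Transcription factors and chromatin genes also went both ways. Of the homeobox and developmental factors, 3 were higher and 5 lower (3 and 3 at the equal minimum), with POU2F2 at 5.91, ZIC1 at -4.16, IRX6 at 2.80 and TBX10 at -2.50 in the authors' deposited table. Of the zinc finger proteins, 3 were higher and 13 lower, with ZNF385C at -3.05, ZSCAN23 at -2.64, ZBTB32 at -2.38 and ZSCAN5A at -1.91 in the authors' deposited table. Of the chromatin regulators, CHD5 stood at -3.61, CHD8 at 2.43 and PRDM16 at -1.92 in the authors' deposited table. The histone list held H2AFY2 at 1.54 and the H4 genes HIST2H4B and HIST1H4K, each of which has a near-identical copy elsewhere, at -1.56 and -1.41 in the authors' deposited table. Among immediate early genes, ARC was at -2.55, KLF4 at -1.60 and KLF2 at 1.54 in the authors' deposited table.

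Of the lists of blood lineage markers, some had members in the authors' deposited table and others had none. No erythroid gene appeared among the 44 on that list, which holds the globins and GATA1, and none of 34 haematopoietic transcription factors appeared. At the share of all annotated protein-coding genes, only 1.6 and 1.3 members would appear. These absences are therefore not read as a contrast between lineages. All 5 myeloid and monocyte genes in the authors' deposited table were lower, with FCGR1A and FCER1G at -1.82 each, CD14 at -1.73 and CLEC7A at -1.27; 3 of them were left at the equal minimum. With 69.2% of the other genes lower, even this most extreme split of 5 gives p = 0.330 by Fisher's exact test, so the test could not pass in this direction. FCGR1A shares sequence with FCGR1B. Of the megakaryocyte and platelet list, the chemokine PPBP was at 3.89, GP1BA at -1.96 and ITGA2 at -1.28 in the authors' deposited table. Of the lymphoid list, the T cell kinase ZAP70 was at 2.69, NCR1 at -1.55 and CD247 at -1.48 in the authors' deposited table. The fibroblast and mesenchymal list held PDGFRB at -3.40, THY1 at -2.18 and TAGLN at -1.43, and the endothelial list held ENG at -2.64 in the authors' deposited table. None of the 20 epithelial and 32 testis and germline genes on their lists appeared. Both lists are incomplete, so this does not show that no gene of these tissues was listed.

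Of all annotated protein-coding genes, 3.71% were in the authors' deposited table, a share at which 36 genes would give 1.3 members and 88 genes 3.3. The absence of any single list is therefore not read as a result. At this share, the 9 lists without a member would each give 0.5 to 3.3 members. That all of them are absent together is less expected than the absence of 1 list, but this was not tested. None of the 46 cell cycle, 42 apoptosis, 88 ribosomal protein, 13 mitochondrially encoded and 36 antigen presentation genes appeared. The interferon list held CXCL10 alone, at -2.28, out of 35 genes, and the JAK-STAT and BCR-ABL list held STAT4 alone, at -2.46, out of 32 in the authors' deposited table. In the authors' deposited table the phosphatase DUSP18 was at -1.42 for the MAPK list, and HSPB9 and DNAJC22 were at -1.63 and -2.68 for the heat shock and unfolded protein list. Of the glycogen and phosphorylase kinase list, PYGM, the muscle glycogen phosphorylase, was at -2.07 in the authors' deposited table. An absent gene had not been selected into the list, which does not show that its level was equal in both groups.

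Across the 37 lists, 190 of the 742 symbols belonged to at least 1 list and 9 lists had no member. In 13 lists with at least 5 members, the split into higher and lower was compared with that of all other genes by Fisher's exact test, two-sided. With Benjamini-Hochberg adjustment over the 13 tests, 0 lists passed 0.05, and 0 passed it unadjusted; the smallest adjusted p of the exact tests was 0.599. In short lists only an excess of higher genes could have passed. This test treats genes as independent and compares directions among selected genes, so it says nothing about enrichment.

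Genes of the authors' deposited table lay on each of chromosomes 1 to 22 and X, and 1 gene, PCDH11Y at 1.71, lay on chromosome Y. PCDH11Y is matched over 100% of its longest transcript by PCDH11X, so this entry does not show expression from chromosome Y. With HMRHL in an intron of PHKB, on chromosome 16 from 47461123 to 47701523, that chromosome was examined by name. It held 29 of the located genes, 5 higher and 24 lower, which was 3.91% of the genes against 4.29% of annotated protein-coding genes. The nearest to PHKB was IRX6, a homeobox gene 7622 kb downstream at 2.80, followed by ADGRG5 at -2.22 and ADGRG3 at -2.39 in the authors' deposited table. On the other side, SLC5A2 (1.53) and TGFB1I1 (-3.30) in the authors' deposited table lay 15970 kb and 15983 kb away. By Fisher's exact test of direction, 0 of 22 chromosomes passed 0.05 after adjustment; 2 passed it unadjusted. These were chromosome 4, with 13 higher and 11 lower genes (exact p = 0.0216, adjusted p = 0.454), and chromosome 2, with 20 higher and 24 lower (exact p = 0.0412, adjusted p = 0.454).

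**Figure D3:**
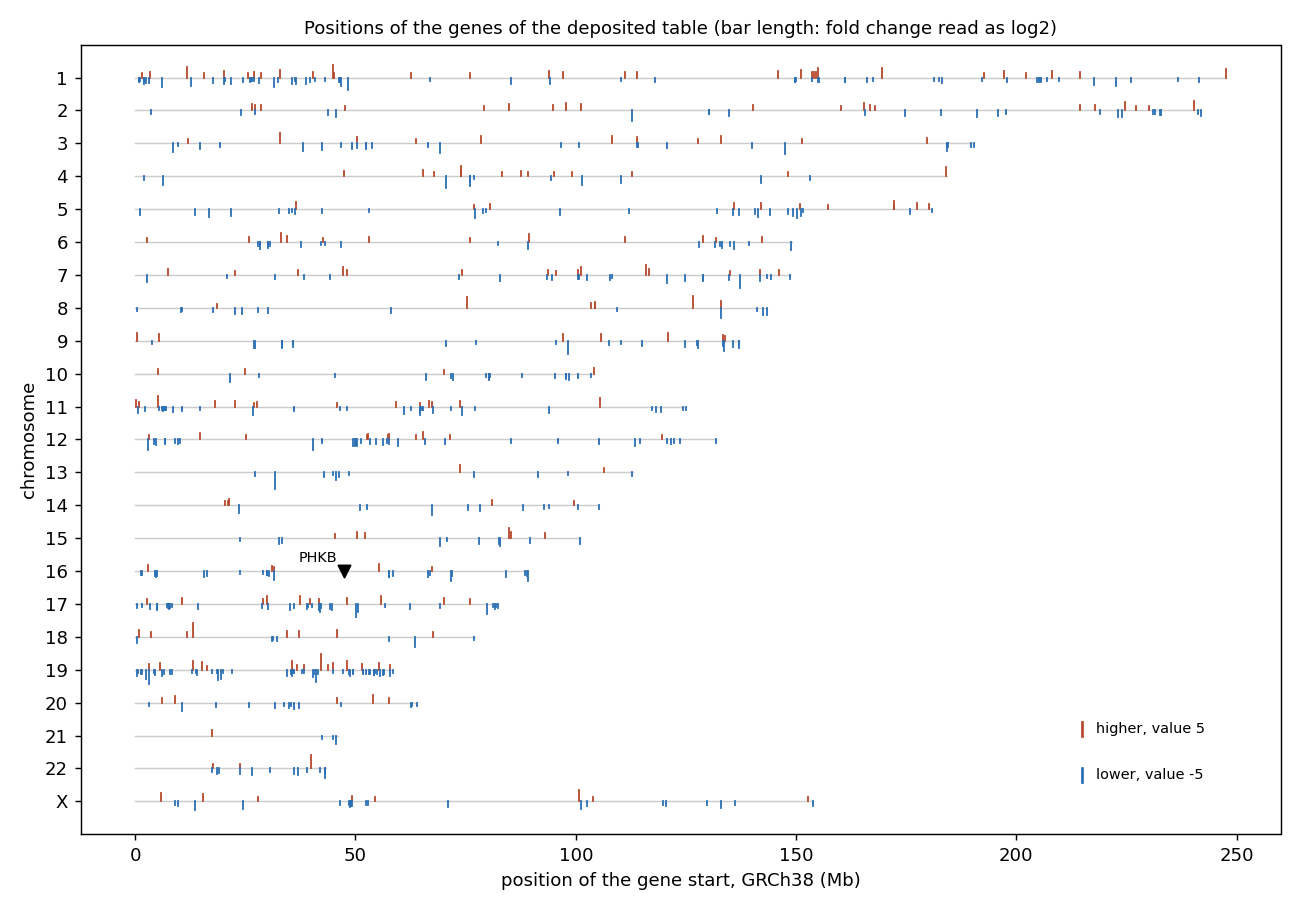
Start positions of the genes of the authors' deposited table on chromosomes 1 to 22 and X (GRCh38, in Mb on the x axis); bars above a line are higher and bars below it lower in the knockdown, and their length is proportional to the fold change read as log2. The triangle marks PHKB on chromosome 16, with IRX6 as the nearest listed gene. The 1 listed gene on chromosome Y, PCDH11Y, is not drawn.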

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

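The overall direction and the calls of lists and chromosomes did not change. The majority turned to higher for ion channels (13 of 20 lower, then 6 of 13 at an equal minimum and 3 of 7 at 4-fold). It also turned for matrix genes (8 of 15, then 6 of 13 and 3 of 8). Adhesion genes, even before, became mostly higher in both settings. They were 4 higher and 5 lower without near-identical copies, which leaves out PCDH11Y. An equal minimum removes only lower genes, so it can shift a list only toward higher. At a minimum of 4-fold 126 higher and 192 lower rows remained of 239 and 592, and the share of lower rows went from 71.2% to 60.4%. Counted once per symbol the split was 227 to 515 (69.4% lower), and without genes that have near-identical copies it was 237 to 574 rows (70.8% lower). At an equal minimum in both directions, added after seeing the data, it was 239 to 400 rows (62.6% lower), and the median absolute log2 value of lower genes rose from 1.71 to 2.03. The count of gene lists past an adjusted p of 0.05 by Fisher's exact test was 0 with every gene, at 4-fold, with older symbols translated, at an equal minimum, without near-identical copies and without olfactory receptors. That of chromosomes was 0 in the 4 settings run for them. Some lists fell under 5 members at 4-fold, at an equal minimum or without near-identical copies and could not be tested there. Alternatives that need expression levels, p-values or values per library (minimum level, pseudocounts, genes at 0, a stricter p, other tools, leaving out replicates) and the comparison of starting levels were not run. No paired analysis was possible because the table holds 1 value per gene for both groups and none per replicate number.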

Other observations

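The families named here, and all tests in this part except those of neighbouring genes and the first tests of 4 gene properties, were chosen after the values were seen. Of the collagen chains in the authors' deposited table, 5 were higher (COL11A2 3.25, COL28A1 2.21, COL17A1 2.05, COL9A2 2.03 and COL4A3 1.67) and 1 lower (COL9A3 -1.43). Against the other genes this gave Fisher's exact p = 0.0117, two-sided, and an adjusted p of 0.0701 over 6 families. All 4 phosphodiesterases in the authors' deposited table, which break down cyclic nucleotides, were lower, with PDE7B at -2.47, PDE1B at -1.78, PDE1C at -1.58 and PDE3B at -1.34 (exact p = 0.319, which no split of 4 genes toward lower could bring under 0.05). Of the pyruvate dehydrogenase kinases, PDK2 and PDK3 were at -4.83 and -3.10 and PDK4 at 1.55 in the authors' deposited table (exact p = 1). Heterotrimeric G protein subunits split into 3 higher, with GNGT1 at 2.02, and 4 lower, with GNA15 at -5.39 and GNG7 at -3.67 in the authors' deposited table (exact p = 0.443).

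Motile cilium proteins split into 3 higher and 10 lower; the axonemal dynein chains DNAH5, DNAH7 and DNAH10 were at -2.17, -1.92 and -1.53, and TEKT4 at 2.16 in the authors' deposited table (exact p = 0.764). Of 10 T cell signalling and surface proteins, 4 were higher, such as CCR4 at 3.77, and 6 lower, such as CD5 at -2.74 and FOXP3 at -1.65 in the authors' deposited table (exact p = 0.504); at an equal minimum of 1.50 in both directions 4 higher and 2 lower were left. Of 10 olfactory receptors 9 were lower, and 8 of the 10 lie on chromosome 11; OR52A1 was the exception at 4.10 in the authors' deposited table (exact p = 0.298 against the other genes). At the equal minimum 1 higher and 1 lower olfactory receptor were left, so the split rests on values nearer to 0 than those of any higher gene. Genes with a near-identical copy were lower in 18 cases (such as SPDYE2 and CYP2A6) and higher in 2 (CSAG3 and PCDH11Y). Among the rest 497 were lower and 225 higher (Fisher's exact p = 0.0483, two-sided, not adjusted). At the equal minimum 12 lower and 2 higher genes with a copy were left (exact p = 0.0541). Reads of those 20 genes can be shared with their copies; FAM156A, for example, is matched over 100% of its longest transcript by FAM156B.

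The repeated rows may come from a join to an annotation that includes alternate haplotype sequences. The 37 repeated symbols added 89 rows, and 59 of these came from 8 genes in 2 regions with many alternate haplotypes, on chromosome 6 from 28 to 34 Mb (MDC1, RNF39, TRIM10 and COL11A2) and chromosome 19 from 54 to 55 Mb (NCR1, TMC4, TTYH1 and LILRB3). There, 8 of 10 listed genes were repeated, against 29 of 731 elsewhere (Fisher's exact p = 7.45e-10, two-sided); NCR1 alone filled 18 rows. Elsewhere 28 symbols filled 2 rows and CCL3 filled 3, and the cause of these was not tested. No biological explanation was tested.

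More genes were listed lower than higher. Repeated rows as the whole cause are argued against by the count per symbol, with 69.4% lower (exact 95% interval 66.0 to 72.7). The lower entry minimum for negative values accounts for part, but at an equal minimum 59.9% were still lower (55.7 to 64.0), although genes are not independent and the interval covers counting only. Normalization between the groups, unequal depth and a real excess of reduced transcripts stay open, since no value per library was analysed here.

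Genes listed as higher were longer and poorer in GC than those listed as lower. The median span was 48.6 kb for 226 higher and 27.0 kb for 515 lower genes (permutation p = 0.00106 adjusted over 4 properties), and the median GC content of the longest transcript was 48.6% against 52.9% (adjusted permutation p = 0.00106). The longest transcript was also longer, at a median of 4130 against 3410 bases (adjusted permutation p = 0.00225), while annotated exons, at 23 against 20, did not pass (adjusted permutation p = 0.135). In tests chosen afterwards, the entry minimum was not the whole cause of either difference (adjusted permutation p = 0.0175 for each at an equal minimum), and each property carries part of the other. With directions permuted within quartiles of GC content, 0.317 of the 0.847 log2 units between the median spans were kept (permutation p = 0.0176 for the rest). Within quartiles of span, -1.99 of -4.29 percentage points of GC content were kept (permutation p = 0.0423). A length or GC bias between the libraries may cause this and so may a biological difference between the gene sets; these stay open, since libraries and unselected genes were not analysed here.

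The hypothesis that listed genes near each other share a direction was not borne out, though the power of the test for a small excess was not measured. Of 298 adjacent pairs within 1 Mb, 61.1% shared a direction, against 57.6% when directions were permuted (permutation p = 0.224), and leaving out overlapping pairs (p = 0.218) or near-identical copies (p = 0.262) gave like values.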
